A study of Mus musculus with 8 samples.

How the data were processed

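Total RNA of whole bone marrow from 4 Gfi1-/-;Id2+/- and 4 Gfi1-/- mice was labelled for Affymetrix Mouse Gene 1.0 ST arrays, and RT-PCR was made on lineage-negative bone marrow cells. The array values are log2 intensities deposited by the authors, and Partek 6.6 is named in the submitters' processing notes; the background, summary and normalization methods are not given in the sources used here. They form 241576 rows, 1 per probe set number, from 3.21 to 14.30, with medians of 7.30 to 7.41 per array. Their scale was read from this range. The lower quartiles differ between arrays, from 5.32 to 5.59, so the arrays had not been left with equal distributions. The rows fall into 28926 runs of consecutive numbers, of which the longest holds 6550, and 3256 rows are identical on all 8 arrays to another row. No table given here pairs the numbers with genes.

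The raw RT-PCR values are threshold cycles (Ct) deposited by the authors, 3 wells per gene and preparation, from 500 ng of RNA with TaqMan probes and 45 cycles, per the file headers and the methods sheet that came with them. The authors also deposited a normalized table, on a log2 scale, headed as differences to Gapdh, and a table of fold changes, called ratios of test to control, whose control is not stated. Negative folds were read as minus the inverse ratio. The sheet defines the difference as target Ct minus reference Ct. The Ct wells of each gene and preparation were averaged, and the level of a gene was the mean Gapdh Ct minus the mean target Ct. The raw table was chosen over the normalized one after both were seen, because it is the source the sheet names. Wells of the same gene and preparation had a pooled SD of 0.171 cycles. Among the raw wells, 1 Gapdh well of a wild-type preparation is undetermined. The 3 wild-type preparations match no sample with labels and were not used in any test; they appear only as values of the authors' deposited table. The 6 mutant preparations were placed by genotype and number.

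Genotypes were compared as Gfi1-/-;Id2+/- minus Gfi1-/-. On the arrays, limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all rows, adjusted p under 0.05) was fitted per probe set on all 8 arrays without a block and without a filter. The plan had been a fit per gene, tests of 21 gene lists with limma's camera, and values of Id2 and Gfi1 on the arrays. None of these could be made without gene names, and probe sets took the place of genes. The rule for named genes was the 15 largest changes in each direction among those past the threshold or, where none passed, the 5 with the smallest p, and each RT-PCR gene. Because the probe sets have no names, only 2 per direction are printed. Before the data were examined, the alternatives were fixed as the mouse number as a block, quantile normalization, median centring, leaving out the dimmest 33.3% of rows, a trended and robust prior, a plain per-row test, other thresholds, leaving out each mouse, and for RT-PCR the linear scale and leaving out each preparation. Added after seeing the data were the means of runs of consecutive numbers, fits without the longest run, odd against even mouse numbers as a block and each set alone, a blocked fit without Gfi1-/- mouse 3, and for RT-PCR the authors' normalized values under both sets of names, Ct without a reference, limma across genes and pairing by number.

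The mouse numbers were checked as pairs. Deviations from the group means correlated between the arrays of the same number at 0.235, 0.356, 0.372 and 0.484 over all rows, each above 0.1, so the numbers were taken to pair the arrays. The pairing comes from the data, and nothing in the labels says what a number shares. Arrays of another number but the same parity also correlated, at a mean of 0.294 (0.192 to 0.341). The bar of 0.1 therefore does not tell pairing by number from pairing by parity. Those of opposite parity correlated at a mean of -0.324. Deviations cancel within a group, so positive values for the same parity bring negative ones for the opposite parity.

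RT-PCR genes were compared with an exact two-sided permutation test over the 20 assignments of 3 against 3 preparations, adjusted by Benjamini-Hochberg over 11 genes, and for the 6 genes of the erythroid list over the list alone. The test was planned on the Ct scale. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used. To compare the RT-PCR tables, each normalized column was set against the raw Ct of each gene minus that of each possible reference, with a tolerance of 0.1.

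The array test was checked on simulated data with 200 of 241576 rows changed. At a log2 difference of 2 it recovered 65.5% with independent arrays and 63.5% with the measured arrays regrouped so that 2 pairs changed sides; at 3 it recovered 87% and 89%. With the block it recovered 0% and 39% at 2, and 60% and 85.5% at 3. The median SE of a probe set's difference was 0.22 on the log2 scale. The mice are individual animals per the labels; what separates the RT-PCR preparations is not stated, so their p-values measure only the spread between these preparations.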

Results

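Gene expression was compared between mice that lack Gfi1 and mice that lack Gfi1 and also carry only 1 intact copy of Id2. Gfi1 is a zinc-finger transcriptional repressor of blood cell development. Id2 is a helix-loop-helix protein without a DNA-binding domain that binds E proteins and keeps them from DNA. The comparison asks what the loss of 1 Id2 copy changes in bone marrow without Gfi1. Whole bone marrow of 4 mice of each genotype was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse, from 100 ng of RNA. Quantitative RT-PCR of 11 genes and the reference Gapdh was made in lineage-negative bone marrow cells, the fraction left after cells with markers of mature lineages were depleted. It covered 3 preparations of each of these genotypes and 3 wild-type preparations. The mutant RT-PCR preparations and the arrays share genotypes and numbers in their names, but they are of different cell fractions and nothing says that they came from the same mice, so each assay was analysed on its own. The precision of every value is limited by 4 mice per genotype on the arrays and 3 preparations per genotype in the RT-PCR.

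Id2, the gene that differs between the genotypes, gave less transcript relative to Gapdh in each of the 3 Gfi1-/-;Id2+/- preparations than in any of the 3 Gfi1-/- preparations. Its level, given as the mean Gapdh Ct minus the mean target Ct so that 1 cycle is 1 unit of log2, was -9.28 ± 0.47 (SD, n = 3) in Gfi1-/-;Id2+/- cells and -7.71 ± 0.63 (SD, n = 3) in Gfi1-/- cells. The difference of -1.57 on the log2 scale (SE 0.46) is a ratio of 0.338. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 preparations allow, and an adjusted p of 0.55 over the 11 genes. Without a reference the difference was -1.52, and relative to Hbb-b1, from the authors' normalized values under the raw names, -1.30. The SDs in Gfi1-/-;Id2+/- and Gfi1-/- cells were then wider, 0.96 and 1.40 without a reference and 0.67 and 0.76 relative to Hbb-b1. In both settings the preparations overlapped. Without a reference the difference was nearly unchanged, so the overlap went with the wider spread. Relative to Hbb-b1, itself a measured gene, the difference was also smaller, and the overlap does not tell a smaller difference from a wider spread. The exact permutation test gave p of 0.3 and 0.2. With 3 preparations per genotype no gene could pass this test, and values are given below without a call. In limma across the same 11 genes, chosen after the data were seen, Id2 had an adjusted p of 0.0648. Gfi1 transcript was at -7.10 ± 0.38 (SD, n = 3) in Gfi1-/-;Id2+/- cells and -7.02 ± 0.11 (SD, n = 3) in Gfi1-/- cells. Both genotypes lack Gfi1, and where its assay lies relative to the deleted part is not given in the sources used here, so this value does not check the deletion.

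None of the erythroid genes could be called different between the genotypes. Relative to Gapdh, all 6 measured members of the list had a lower mean in Gfi1-/-;Id2+/- cells. Tfrc had the higher mean there without a reference, by 0.033, and relative to Hbb-b1, by 0.23. Relative to Gapdh, 0 of the 6 passed the test, adjusted over the list alone or over all 11 genes. The mean of the 6 genes differed by -0.34 on the log2 scale (SE 0.48), with p = 0.4 in the exact two-sided permutation test. Gfi1b, a repressor related to Gfi1 that acts in erythroid and megakaryocytic cells, differed by -0.64 (SE 0.26). Relative to Gapdh its preparations did not overlap, with an exact permutation p of 0.1. They overlapped without a reference (-0.60, exact permutation p = 0.6) and relative to Hbb-b1 (-0.37, exact permutation p = 0.8). Ct without a reference keeps the spread of Gapdh Ct, with SDs of 1.03 and 0.81 cycles in the 2 genotypes. Hbb-b1 is itself 1 of the 6 erythroid genes, with SDs of 0.99 and 0.89 relative to Gapdh. Overlap in these settings therefore does not weigh against the difference relative to Gapdh. Without Gfi1-/- preparation 3 the Gfi1b difference relative to Gapdh was -0.43 (exact permutation p = 0.2). Gata1, the main erythroid GATA factor, differed by -0.43 (SE 0.31) and Klf1, an activator of the adult beta-globin gene, by -0.43 (SE 0.87). Epor, the erythropoietin receptor, differed by -0.29 (SE 0.74), the globin gene Hbb-b1 by -0.23 (SE 0.77), and Tfrc, the transferrin receptor, by -0.01 (SE 0.37). The wide errors of Klf1 and Epor went with 1 preparation. Klf1 stood at -7.27 in Gfi1-/- preparation 2 and at -4.77 and -4.63 in the other 2, and Epor at -8.40 against -6.30 and -6.20. The mean of the 6 erythroid genes depended on single Gfi1-/- preparations: it differed by -0.81 without preparation 2 (exact permutation p = 0.1), by -0.13 without preparation 1 and by -0.08 without preparation 3 (exact permutation p = 0.8 for each). With 1 preparation left out the permutation test compares 3 preparations with 2, and 0.1 is again its smallest p. With the preparations averaged on the linear scale, Klf1 differed by -0.81, Epor by -0.555 and Tfrc by -0.08 as log2 of the ratio. On the Ct scale, Epor turned to 0.044 without Gfi1-/- preparation 1 and to 0.094 without Gfi1-/- preparation 3, and Klf1 to 0.028 without Gfi1-/- preparation 3. Hbb-b1 turned to 0.34 without Gfi1-/-;Id2+/- preparation 2 and to 0.18 without Gfi1-/- preparation 1. Tfrc turned to 0.10 without Gfi1-/-;Id2+/- preparation 1 and to 0.29 without Gfi1-/- preparation 3.

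Gata2, a factor of stem and progenitor cells, was at -4.21 ± 0.18 (SD, n = 3) in Gfi1-/-;Id2+/- cells and -3.76 ± 0.29 (SD, n = 3) in Gfi1-/- cells, a difference of -0.46 (SE 0.20) with an exact permutation p of 0.2. Of the 2 cell cycle genes, the cyclin gene Ccne1 differed by -0.41 (SE 0.40) and the kinase gene Cdk1 by 0.29 (SE 0.62), with exact permutation p of 0.6 and 0.7. Without Gfi1-/-;Id2+/- preparation 1 the Ccne1 difference was -0.02. With Hbb-b1 as the reference, Gata2 differed by -0.27, Ccne1 by -0.13 and Cdk1 by 0.53, with exact permutation p of 0.6, 0.9 and 0.3. Cdk1 alone of the 11 genes had a higher mean relative to Gapdh in Gfi1-/-;Id2+/- cells, but not without Gfi1-/- preparation 2, where it differed by -0.26. Relative to Gapdh, groups did not overlap for 2 of the 11 genes, Id2 and Gfi1b, where chance gives 10% of genes. Without a reference, or relative to Hbb-b1, this held for 0 genes, but the preparations of Id2 and Gfi1b then spread more widely. For Gfi1b the SDs in Gfi1-/-;Id2+/- and Gfi1-/- cells were 0.20 and 0.40 relative to Gapdh. They were 1.23 and 1.16 without a reference, and 1.18 and 0.79 relative to Hbb-b1. Gapdh itself was at 15.82 ± 1.03 cycles (SD, n = 3) and 15.87 ± 0.81 cycles (SD, n = 3) in the 2 genotypes, with an exact permutation p of 1.

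**Figure D1:**
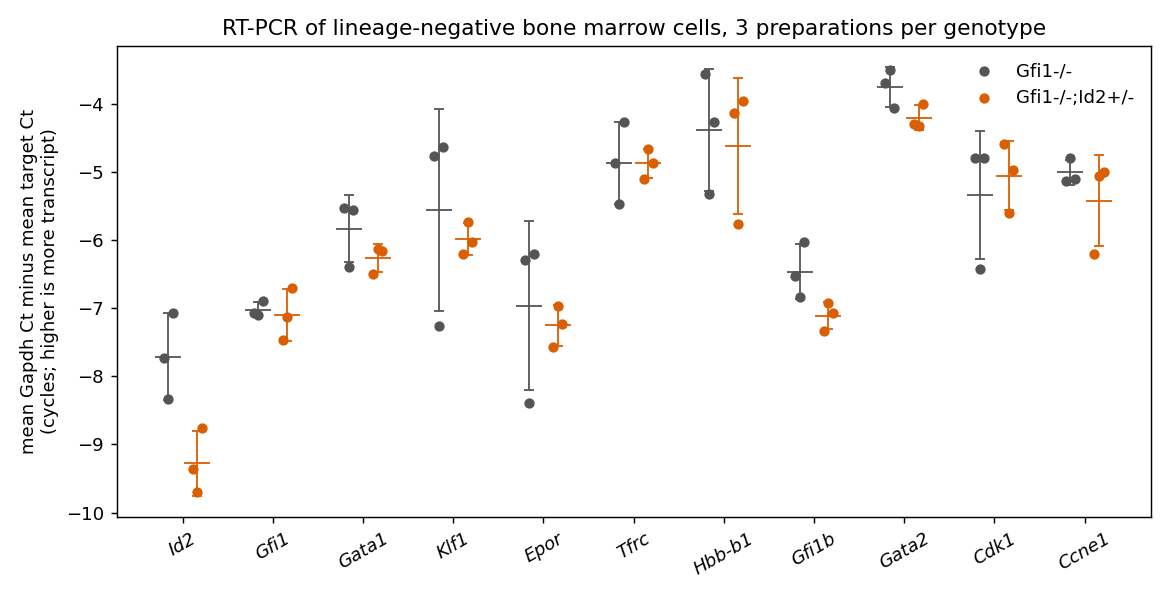
Level of each of 11 genes in lineage-negative bone marrow cells, as mean Gapdh Ct minus mean target Ct in cycles on the vertical axis. Points are the 3 preparations of each genotype, and bars are the mean and SD. Only Id2 and Gfi1b show groups that do not overlap, and Gfi1-/- preparation 2 is the low point of Klf1 at -7.27.

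These values rest on the gene names of the raw Ct table, because the RT-PCR tables do not name the genes alike. With the same names in both tables, 0 of 66 values of the authors' normalized table lay within 0.1 of the raw Ct of the gene minus that of Gapdh. All 66 lay within 0.1 of the raw Ct of a gene minus the raw Ct named Hbb-b1 once the 12 names were put in another order. That order is obtained by sorting the detector numbers of the raw table as text, and it held for 12 of 12 columns. Ccne1 alone kept its name. The column named Id2 held the wells named Cdk1 in the raw table, Gata1 held those named Id2, Tfrc held those named Gapdh, and Gapdh held those named Hbb-b1. In the raw table Gapdh had the lowest Ct of the 12 genes in 6 of 6 preparations, 14.77 to 16.83 cycles, and the next lowest gene value was 19.00 cycles. Under the normalized table's names, and with its sign turned so that more transcript is higher, Id2 differed by 0.53 (SE 0.42) in place of -1.57, with an exact permutation p of 0.3.

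**Figure D2:**
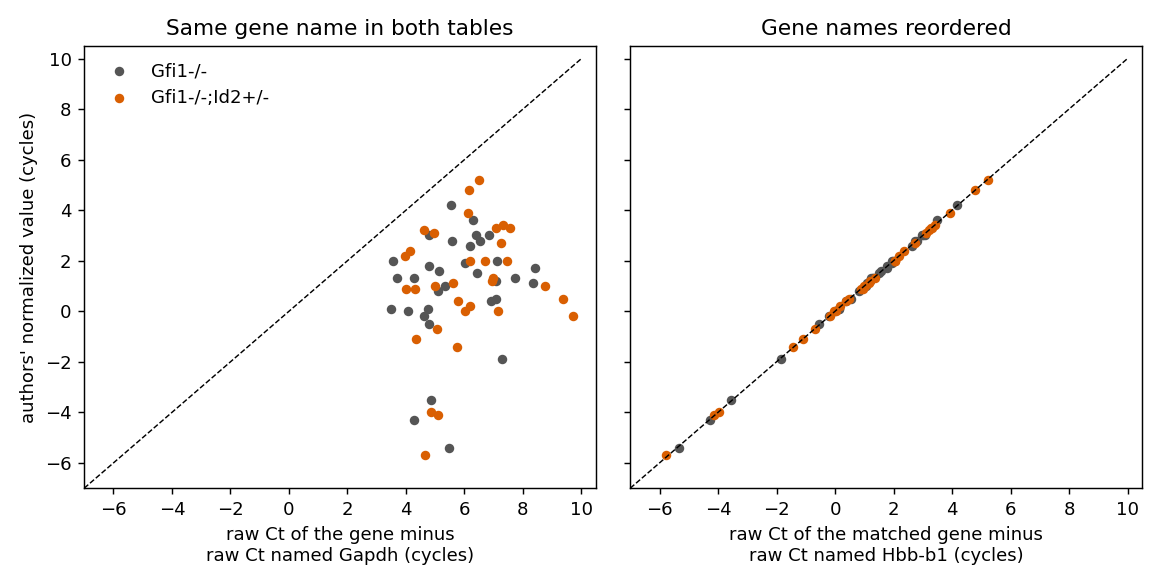
The authors' normalized values on the vertical axis against differences of raw Ct on the horizontal axis, both in cycles, for 11 genes in 6 preparations coloured by genotype, with the line of equality dashed. With the same gene name in both tables (left) 0 of 66 points lie within 0.1 of the line, and with the names reordered and Hbb-b1 as the reference (right) 66 of 66 do.

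The fold changes given for wild-type, Gfi1-/-;Id2+/- and Gfi1-/- preparations carry the same doubt. In the authors' deposited table the column named Gata1 held 54.3, 36.4 and 58.8 for wild-type, 36.5, 25.4 and 27.7 for Gfi1-/-;Id2+/- and 18.3, 7.9 and 6.9 for Gfi1-/- preparations. The column named Id2 in the authors' deposited table held 1.4, 1.7 and 2.0 for wild-type, 1.4, 1.1 and 2.0 for Gfi1-/-;Id2+/- and 2.4, 2.1 and 2.5 for Gfi1-/- preparations. On the log2 scale, 39 of 66 folds of the authors' deposited table for the mutant genotypes lay within 0.1 of the normalized value of the same column. Of the 11 genes, this held for 1 in Gfi1-/-;Id2+/- preparation 2, for 5 in Gfi1-/- preparation 1, and for 8 or 9 in the others. With the sign of the normalized value turned, as a relative quantity from a Ct difference needs, 8 of 66 folds of the authors' deposited table lay within 0.1 of it. No gene's direction was therefore read from the fold values, nor from the normalized values under their own names.

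On the arrays no probe set passed the test between the genotypes. With limma, 0 of 241576 probe sets had an adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 6791 probe sets, 2.81% of those tested, where chance alone gives a share of 0.05. The genotypes did not overlap in 1.5% of probe sets, where chance gives 2.86%. The difference between odd-numbered and even-numbered mice, given below, lies within each genotype and widens the spread there. Shares under those of chance are therefore no sign that the genotypes differ less than chance. With odd against even as a block, 4.93% of probe sets had an unadjusted limma p under 0.05. Of the 6791, 2114 had the higher mean in Gfi1-/-;Id2+/- mice and 4677 the lower. This balance went with the fit: it was 4436 and 4993 without Gfi1-/- mouse 3, and 2774 and 3989 after median centring. A plain per-row test gave 0 and 6409. With the mouse number as a block, limma again gave 0, with 14141 (5.85%) at an unadjusted p under 0.05, 5997 higher and 8144 lower. On simulated independent arrays limma found 0% of 200 changed probe sets at a log2 difference of 1, 65.5% at 2 and 87% at 3. With the block it found 0% at 1, 0% at 2 and 60% at 3, but such arrays lack the correlation between arrays of the same number. On the measured arrays, regrouped so that 2 pairs changed sides, the block found 0% at 1, 39% at 2 and 85.5% at 3. Changes of 1 in 200 probe sets were thus not found with 4 mice per genotype, nor, with the block, those of 2 on independent arrays. This limit holds for 200 changed probe sets and was not simulated for more. Between odd-numbered and even-numbered mice, with genotype in the model, 22440 probe sets passed, with a median absolute difference of 0.79.

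The probe sets are listed by number and the files do not pair the numbers with genes, so Id2, Gfi1, the erythroid genes and other gene groups were not read from the arrays. The lower probe sets with the smallest p were 10586940, at 6.01 ± 0.21 (log2 intensity, SD, n = 4) in Gfi1-/-;Id2+/- and 7.48 ± 0.34 (SD, n = 4) in Gfi1-/- mice, and 10434164, at 5.96 ± 0.19 and 7.04 ± 0.19. The higher ones were 10372276, at 6.28 ± 0.20 and 5.22 ± 0.16, and 10570312, at 5.48 ± 0.26 and 4.19 ± 0.26. All 4 had a limma adjusted p of 1, and 0.835 with the mouse number as a block; without Gfi1-/- mouse 1 it lay between 0.118 and 0.206.

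The arrays parted by the number of the mouse more than by genotype. A split into the 4 odd-numbered and the 4 even-numbered mice, each set holding 2 mice of each genotype, gave 26873 probe sets with a limma adjusted p under 0.05. With genotype in the model there were 22440, of which 13505 were higher in odd-numbered mice and 8935 lower. Within the odd-numbered mice alone, 0 probe sets passed between the genotypes (4516 at an unadjusted p under 0.05), and within the even-numbered mice alone also 0 (16543). With odd against even as a block, limma gave 0 and 11904 (4.93%). On the first principal component, which held 42.6% of the variance, the odd-numbered mice lay between -248.8 and -25.2 and the even-numbered mice between 80.6 and 143.2.

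**Figure D3:**
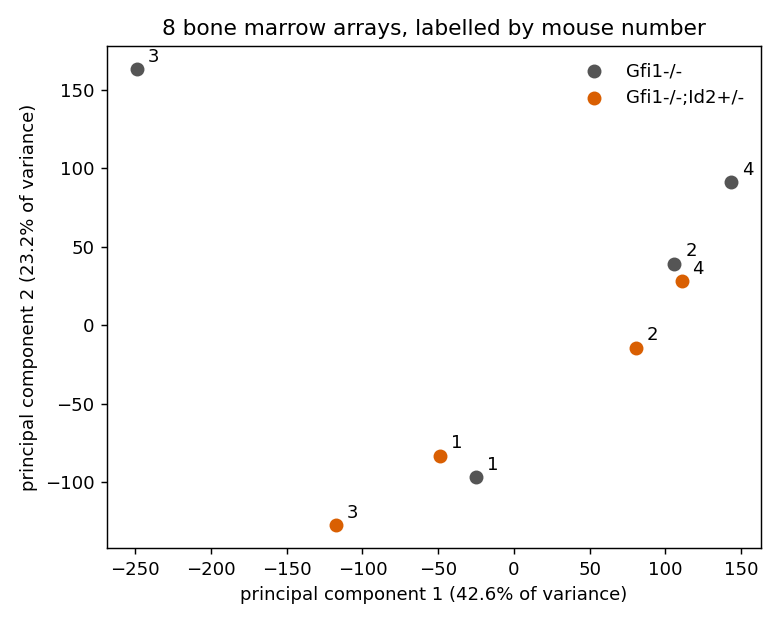
First against second principal component of the 8 bone marrow arrays in arbitrary units, each point 1 mouse, coloured by genotype and labelled by its number. Odd-numbered mice of both genotypes lie at the left, from -248.8 to -25.2, and even-numbered mice at the right, from 80.6 to 143.2; Gfi1-/- mouse 3 lies farthest out.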

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

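The count of probe sets past the threshold was 0 with limma and stayed 0 under each alternative run, planned or added, including the thresholds of 0.1 and of 0.05 with a log2 size of at least 1, and leaving out each mouse (0 to 0). The count at an unadjusted p under 0.05 moved from 6791 to 14141 with the replicate block and ranged from 4903 to 11872 when 1 mouse was left out, the highest without Gfi1-/- mouse 1. The block changed no call. With a real count of 0, each of the 35 splits of the 8 arrays gives as many, so 35 of 35 shows nothing; the highest other split, odd against even numbers, gave 26873. At an unadjusted p under 0.05, 23 of 35 splits gave at least 6791, with a highest other of 73196, the odd-even split. Splits with more odd-numbered mice on 1 side also carry the odd-even difference, unlike the real split. The share of 23 of 35 is therefore no clean measure of chance for the genotypes, and chance cannot be excluded for that count. Of the 8 splits that part all 4 pairs, 2 gave as many as the real 14141 with the block, the highest other being 16653, and 8 splits are too few for a share under 0.05. For RT-PCR, the count of genes past the threshold was 0 under each alternative run, including limma and leaving out each preparation (0 to 0), but the permutation test could not pass. The Id2 difference ranged from -1.88 to -1.24 without 1 preparation, and the erythroid mean from -0.81 to -0.08, lowest without Gfi1-/- preparation 2. Under the normalized table's own gene names, by permutation and by limma alike, Id2 turned to 0.53, Cdk1 to -0.37, Tfrc to 0.20, Epor to 0.20 and Gata2 to 0.23. By its construction that table carries other names and another reference, so these are Ct of other wells. With the names matched to the raw Ct, and Hbb-b1 as the reference, Id2 was at -1.30, Gfi1 turned to 0.20 and Tfrc to 0.23, and without a reference Tfrc turned to 0.033. The last 3 follow from the change of reference alone, since Hbb-b1 itself differed by -0.23 and Gapdh Ct by under 0.1 between the genotypes. Without 1 preparation the ranges crossed 0 for Cdk1 (-0.26 to 0.56), Gfi1 (-0.28 to 0.11), Tfrc (-0.31 to 0.29), Epor (-1.01 to 0.094), Hbb-b1 (-0.71 to 0.34) and Klf1 (-1.29 to 0.028); Ccne1 (-0.62 to -0.02) and Gata1 (-0.72 to -0.28) kept their sign. On the linear scale the 11 genes kept their sign. RT-PCR preparations share only a number: their deviations correlated at 0.566, 0.114 and -0.505, and pairing them in a sign-flip test, whose smallest p is 0.25, passed 0 genes. Not run for want of gene names were both row-to-gene summaries, the gene list tests and Id2 on the arrays. Gapdh is the only stated reference, so the genotypes were compared with no other reference than Gapdh and Hbb-b1. Hbb-b1 is itself among the erythroid genes measured, so it is no independent reference for them.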

Other observations

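The tests in this part, except Dixon's test, were chosen after the results were seen. The structure of the arrays that the genotypes leave unexplained showed itself in groups of neighbouring probe sets. Of 18894 runs of at least 3 consecutive numbers, 6180 differed between odd-numbered and even-numbered mice at a limma adjusted p under 0.05, with genotype in the model. In 2 of them the difference was 3 or more on the log2 scale. A run of 11 probe sets averaged 11.97 in the 4 odd-numbered mice, from 11.32 to 12.84, and 6.01 in the 4 even-numbered mice, from 5.79 to 6.11. A run of 5 went the other way, averaging 7.21 (6.62 to 7.91) in odd-numbered and 12.08 (11.59 to 12.56) in even-numbered mice. The same runs differed by 0.00 and 0.16 between the genotypes. Their genes are not named in the files used here.

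Unequal intensity distributions are not the whole cause of the difference between odd-numbered and even-numbered mice, since 13948 probe sets passed the threshold after quantile normalization, against 22440 before. Noise of single probe sets is argued against by a correlation of 0.40 between neighbours in a run, where neighbours across a gap had 0.07. Array labels in another order than the genotypes, for instance alternating, would make the odd-even split the larger one, as it was with 26873 probe sets against 0, but a shared batch, a litter or the sex of the mice could give the same. These cannot be told apart, since the sources used here give no gene names, sexes or batches. No biological explanation was tested, since the design names no other difference between the mice.

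Gfi1-/- mouse 3 lay farthest from its group of the 8 arrays, though Dixon's test did not set it apart from the other 3 Gfi1-/- mice: its gap over the group's range was 0.816 for the mean correlation with its group and 0.741 for the SD of its deviation, both under the critical value. Its deviation from its group had an SD of 0.74 on the log2 scale, where the others had 0.39 to 0.51, and 33259 of its probe sets were off by at least 1. After quantile normalization the SD was 0.738, above the other 7, which argues against the intensity distribution. Its deviations correlated at 0.535 between neighbours in a run and 0.052 across gaps, which argues against noise of single probe sets. A difference of the animal or of its sample stays open and was not tested; without this mouse limma again called 0 probe sets between the genotypes.

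The mismatch of the RT-PCR tables was set against 3 explanations. A constant per gene and per preparation left an SD of 0.819 cycles, against an error of 0.12 cycles from the wells, and is argued against. Gene names in another order with another reference gave 66 of 66 values to within 0.1, and no reference other than Hbb-b1 gave 1 whole column. A candidate cause is that columns were sorted by detector number as text and then named in numeric order, since this gives 12 of 12 names. Whether the raw table could hold the wrong names was tested on Id2 alone, which does not settle it. Under the normalized names Id2 would be higher by 0.53 (SE 0.42) in the mice with 1 intact copy of Id2, which is under 2 standard errors. The wells of lowest Ct in 6 of 6 preparations would under those names be Tfrc and not Gapdh. Tfrc Ct would then lie 4.0 to 5.7 cycles below Gapdh in Gfi1-/-;Id2+/- and 3.5 to 5.4 cycles below it in Gfi1-/- preparations.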
